A study of Mus musculus with 48 samples.

How the data were processed

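Gene expression in whole blood was measured on 48 single-colour Agilent whole mouse genome arrays, 1 array per sample. Per the labels, the animals were males of the inbred strain C57Bl/6, 3 months old, and the exposed ones were given 8 ± 0.3 MBq of caesium-137 chloride in 50 µL by a single injection into the peritoneal cavity. Caesium-137 emits beta particles and gamma rays and spreads through soft tissue, so the dose accrues as the days pass. Blood was drawn from the heart, 400 µL of it was kept in an RNA stabiliser (PAXgene), alpha- and beta-globin transcripts were depleted with the GLOBINclear kit, and 100 ng of RNA was labelled with the dye Cy3.

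The deposited scanner files hold a fluorescence intensity for each spot, and the processed signal in them is that intensity after the scanner software, Agilent Feature Extraction, had subtracted background and removed trends across the array. The submitters' processing notes name version 9.1.3.1 of that software, while version 10.7.3.1 is given per the file headers. The deposited series table holds log2 values. Each of its columns equalled the log2 processed signal of its array plus 1 constant, within 0.001 for 98.1% to 98.9% of the values in a column, and the other spots of the array were blank (10796 to 31886 values per column). The constants ran from -0.64 to 1.62 and the column medians from 6.39 to 8.62, so the columns are on a log2 scale and are not centred on 0; how the constants and the blanks were chosen is not stated. All results come from the processed signal, and the series table was used as an alternative only.

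Control spots were left out, as were values of spots that the scanner software had marked as outliers. The remaining 43020 spots held 39429 probes, and spots of the same probe were averaged. Probes carry the gene names the files pair with them, updated through a RefSeq table of the mouse assembly GRCm38.p6: 26761 probes matched by transcript accession, 3814 by symbol and 639 by an older symbol, and 8215 kept the name in the file. The array design was built on an older assembly, mm9, so no coordinates were used. Values were put on the log2 scale and the 75th percentile of all probes was subtracted array by array. A probe was kept where it was well above background, as the scanner software marks it, on at least 3 arrays of some group, and each gene was represented by the probe with the highest mean over the 48 arrays, which left 18109 genes.

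The labels give 9 groups: controls on day 3 and day 5 (3 arrays each), day 20 and day 30 (6 arrays each), and exposed mice on days 2, 3, 5, 20 and 30 (6 arrays each). Each exposed group was compared with the controls of the same day. The labels hold no controls for day 2, and the day 2 group was compared with the mean of the day 3 and day 5 control groups. All 48 arrays were fitted together in limma 3.58.1 (R 4.3.3), with 39 residual and 4.36 prior degrees of freedom. Genes with an adjusted p (Benjamini-Hochberg, over all genes of a comparison) at or below 0.05 are said to have changed. Adjusted p-values of single genes are limma's unless another test is named. Further contrasts compared the response on days 20 and 30 with that on days 3 and 5, day 5 with day 3, and day 30 with day 20. Differences among the 4 control groups were tested together.

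The 23 gene lists were written from general knowledge. They hold p53 target genes, DNA repair genes, markers of B cells, T cells, natural killer (NK) cells, neutrophils, monocytes, eosinophils and basophils, reticulocytes and platelets, and primary granule genes of granulocyte precursors. Others hold globin transcripts, cell cycle genes, interferon-stimulated genes, inflammatory and NF-kB genes, MHC class II genes, antioxidant genes, ribosomal protein genes, oxidative phosphorylation genes, proteasome genes, circadian clock genes, immediate early genes, and heart and skeletal muscle markers. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, in 115 tests adjusted within each day. Camera compares a list with the other genes, so a shift common to all genes does not enter it, but an uneven one does. Camera was also run with the correlation estimated from the data and on ranks. Limma's fry tested lists against no change. A score per array, the mean of a list's members, was compared between the groups of each day with an exact two-sided permutation test, adjusted over the lists of the day. The count of members past the threshold is given over all genes and adjusted over the list alone.

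Genes named for each day were the 6 with the largest rise and the 6 with the largest fall among changed genes whose compared groups do not overlap and whose probe was well above background on every array of the brighter group. Added to these were up to 3 members of each list with the smallest p and 16 genes named whatever their values, of which 1 is not reported here. For the contrasts between days, the 5 largest rises and the 5 largest falls were taken. The text names part of these, and that part was picked after their values had been seen. Where a probe was not well above background on any array of a group, the change is given as a bound. For it, each array of that group was set to the gene's value or to the lowest value marked well above background on that array, whichever was higher.

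Arrays came on 12 slides that were read on 4 scan days. Scan day 1 held the exposed day 2 arrays, the day 3 controls and replicates 1 to 3 of the exposed day 3 arrays. Scan day 2 held the other day 3 arrays and all day 5 arrays, and days 20 and 30 each had a scan day of their own. Slide, scan day and replicate number were tried as blocks, and values were taken within the slides that held both groups. Other alternatives were a normexp background, median and quantile scaling, the deposited series table, other probe filters, mean in place of brightest probe, array weights, an intensity trend, other controls, other thresholds, the compared groups alone, and each array left out in turn. The comparisons, lists, naming rule and most alternatives were set before the data were examined. Chosen afterwards were scan day as a block, scaling on probes detected on all arrays, leaving out 3 doubtful arrays, the filter on detection on every compared array and the day 3 comparison within scan day 1. So were the exact test of list scores, the list tests of the contrasts between days, and the definition of overlap between days. Replicates with the same number in the exposed day 2 group and the day 5 controls had correlated residuals (0.27 to 0.47 in 3 of 3 pairs), so the day 2 count is also given with the replicate number as a block. That block was fitted to the compared groups alone.

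The code was tested on simulated data in which, for each day, 126 genes were shifted by 1 and 100 by 2. Of genes shifted by 1 on the log2 scale it recovered 45.2% in the day 2 comparison, 27.8% on day 3, 35.7% on day 5, 52.4% on day 20 and 51.6% on day 30. Of those shifted by 2 it recovered 92%, 85%, 88%, 98% and 96%. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. p-values measure the spread between arrays, which for limma's single genes is pooled over all 9 groups and is not that of the compared day alone. The labels state neither whether each replicate is a different mouse nor how mice were allotted.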

Results

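Blood transcripts were measured on 48 arrays, 18 from control mice and 30 from mice that had received caesium-137 (Cs-137). Exposed mice were sampled on days 2, 3, 5, 20 and 30, at accrued doses of 2, 2.7, 4.1, 9.5 and 9.9 Gy per the labels, with 6 arrays per day. Controls were sampled on day 3 and day 5 with 3 arrays each, and on day 20 and day 30 with 6 arrays each. Time and dose rose together, so the comparisons do not separate them. The share of probes well above background ran from 27.2% to 80.6% over the arrays, and the 75th percentile of the processed signal from 33.6 to 258 intensity units. Group means of that share were 41.6%, 54.1%, 46.5% and 50.5% in the controls of days 3, 5, 20 and 30, and 48.2%, 46.6%, 50.8%, 34.8% and 44.4% in the exposed groups of days 2, 3, 5, 20 and 30. Each comparison asked which transcripts differed between exposed and control blood at that time after the internal exposure began. Values of single genes are log2 fold changes, exposed minus control, ± SE. For lists that camera did not call, counts of members are over all genes tested unless stated.

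On day 2, p53 target genes, platelet genes and NK cell genes were higher, and B cell and MHC class II genes lower, in 6 exposed arrays than in the 3 day 3 and 3 day 5 control arrays. Phlda3, a p53-induced inhibitor of Akt signalling, rose by 1.92 ± 0.21 (adjusted p = 2.18e-07). Ccng1, which encodes cyclin G1, rose by 1.99 ± 0.30 (5 of 6 control arrays well above background), the nuclease gene Aen by 1.5 ± 0.20, Bbc3, which encodes the cell death protein PUMA, by 1.35 ± 0.20 and Bax by 1.17 ± 0.22. In each of these 5 genes all exposed arrays lay above all control arrays. Mdm2, whose product degrades p53, rose by 0.63 ± 0.18 and H2ax, a histone that marks DNA breaks, by 0.81 ± 0.15. Cdkn1a, the p21 inhibitor of the cell cycle, rose by 0.87 ± 0.29 (adjusted p = 0.037, 2 of 6 control arrays well above background) and Trp53inp1 by 0.86 ± 0.27 (adjusted p = 0.0257). Slide as a block ended 25 of the 26 named day 2 calls, the replicate block 19 and the day 3 controls alone 14. Leaving out single arrays ended the call of Cdkn1a in 7 of 12 cases (adjusted p up to 0.0878, without day 5 control replicate 3), of Trp53inp1 in 4 (up to 0.0798, without day 5 control replicate 1) and of Cd79a in 7 (up to 0.118, without day 3 control replicate 1).

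Among 24 measured p53 target genes, 11 were higher and 1 lower on day 2 (13 and 2 adjusted over the list alone, median 0.57), with camera adjusted p = 5.13e-06 and 0.0766 with an estimated correlation. The mean of the list was -0.09 ± 0.09 (SD, n = 6) in exposed and -0.64 ± 0.14 (SD, n = 6) in control arrays. It was higher in 6 of 6 exposed arrays than in any control (exact two-sided permutation p = 0.00216, the smallest that 924 splits allow, adjusted 0.0498). By this test 2 of the 23 list scores differed on day 2, the other being NK genes (adjusted 0.0498), while adjusted p was 0.0664 for platelet, 0.0747 for antioxidant, 0.0913 for MHC class II and 0.178 for B cell genes. Platelet and megakaryocyte genes rose, 23 of 25 (23 adjusted over the list alone, median 1.38), with adjusted p = 1.65e-21 and 0.0961 with an estimated correlation. Thbs1 rose by 1.76 ± 0.26, the ADP receptor P2ry12 by 1.39 ± 0.23 and platelet factor 4 (Pf4) by 1.07 ± 0.25. NK cell genes rose, 10 of 17 (10 adjusted over the list alone, median 0.94), with adjusted p = 1.33e-05 and 0.347 with an estimated correlation, including the receptor gene Klra8 (1.22 ± 0.26). Antioxidant genes rose, 9 of 28 (9 adjusted over the list alone, median 0.28), among them Prdx6 (1.28 ± 0.22) and Srxn1 (1.41 ± 0.28), with adjusted p = 3.05e-04 and 0.544 with an estimated correlation. B cell genes fell, 4 of 26 (6 adjusted over the list alone), with a median of -0.68, adjusted p = 9.88e-05 and 0.544 with an estimated correlation. Cd79a, a chain of the B cell receptor complex, changed by -0.90 ± 0.29 (adjusted p = 0.0286) and the IgE receptor Fcer2a by -0.71 ± 0.20. MHC class II genes fell, 2 of 10 (9 adjusted over the list alone), with a median of -0.73, adjusted p = 2.60e-04 and 0.450 with an estimated correlation. H2-Eb2 was at least 1.43-fold lower, with 0 of 6 exposed and 3 of 6 control arrays well above background.

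Other genes that rose on day 2 were Ctnnal1 (2.21 ± 0.29, well above background on 3 of 6 control arrays), Ccnd1, which encodes cyclin D1 (1.97 ± 0.37, 2 of 6 control arrays) and the erythroid transcription factor Tal1 (1.66 ± 0.22). The T cell adaptor Lat rose by 1.11 ± 0.20 and the erythropoietin receptor Epor by 1.09 ± 0.16, and the immediate early gene Fos was at least 1.77-fold higher. Spns2, a sphingosine 1-phosphate transporter, changed by -1.79 ± 0.31, with 1 of 6 exposed arrays well above background, and Apoc2 by -1.06 ± 0.22. Not called were the B cell gene Ms4a1 (-0.46 ± 0.53) and the T cell gene Cd3e (0.12 ± 0.20). Neither were the neutrophil genes S100a8 (0.40 ± 0.50) and Csf3r (0.21 ± 0.17) and the heme synthesis gene Alas2 (-0.03 ± 0.16). Of the lists that camera did not call, T cell genes had a median of 0.29 (1 of 28 members higher), neutrophil genes 0.38 (1 of 27 higher), primary granule genes 0.44 (2 of 10 higher), and interferon-stimulated genes -0.13 (1 of 35 higher). DNA repair genes had 0.02 (2 of 24 higher) and cell cycle genes 0.04 (3 of 33 higher and 1 lower). Reticulocyte genes (median -0.10, mean 0.05) and circadian clock genes (median 0.04, mean -0.06) had medians and means of opposite sign.

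In all, 2674 genes differed on day 2, 1521 higher and 1153 lower. The day 5 and day 3 control groups differed from each other in 3963 genes, 2767 higher and 1196 lower on day 5, and against the day 3 controls alone the day 2 count was 119, against the day 5 controls alone 6671. With scan day as a block it was 404 (91.1% higher) and with slide as a block 10. In a fit of the compared groups alone it was 3880 (46.8% higher), and 408 (13.7% higher) with the replicate number as a block in that fit. Within the slide that held both groups (2 exposed and 2 control arrays), list medians were 0.40 for p53 targets, 1.02 for platelet, 0.30 for NK, 0.18 for antioxidant, -0.83 for B cell and -0.95 for MHC class II genes, where all genes had 0.04. With slide as a block, the day 5 controls were tied to day 2 only through slides with 1 control array. The count and list tests of that fit cannot support a call. Without day 2 replicate 2 the count was 1751, without day 3 control replicate 3 it was 1656, and without day 5 control replicate 1 it was 1615. The median of all genes was -0.01, and was 0.19 with median scaling and -0.19 with scaling on probes detected on all arrays. 56.9% of the changed genes were higher, against 75.4% and 33.4% under these scalings and 43.4% in the deposited series table.

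On day 3, B cell, MHC class II, monocyte and interferon-stimulated genes were lower, and p53 target and platelet genes higher, in 6 exposed than in 3 control arrays. Phlda3 rose by 2.08 ± 0.26 (adjusted p = 3.35e-06), Ccng1 by 1.75 ± 0.36, Bbc3 by 1.19 ± 0.24, Aen by 1.08 ± 0.24 and Mdm2 by 0.70 ± 0.21 (adjusted p = 0.0351), and Cdkn1a was at least 1.62-fold higher. Fcrla, a B cell Fc receptor-like gene, changed by -2.96 ± 0.49 with 4 of 6 exposed arrays well above background, the B cell scaffold gene Bank1 by -2.58 ± 0.38 with 5 of 6, and the chemokine receptor Ccr6 by -2.27 ± 0.35. Cd79a changed by -1.65 ± 0.35 (adjusted p = 0.0019) and Ms4a1, which encodes CD20, by -2.12 ± 0.65 (adjusted p = 0.0346). These 2 calls and that of H2-Aa (-1.82 ± 0.42) ended without day 3 control replicate 1, at adjusted p = 0.0928 for Cd79a, 0.342 for Ms4a1 and 0.111 for H2-Aa. The Ms4a1 call also ended without day 3 control replicate 3 and without exposed replicates 4 and 5. Bank1, Fcrla and Ccr6 stayed called whichever array was left out.

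Of 26 B cell genes, 14 were lower and none higher on day 3 (19 lower adjusted over the list alone), with a median of -1.51, adjusted p = 4.92e-15 and 0.0626 with an estimated correlation. MHC class II genes fell, 8 of 10 (9 adjusted over the list alone, median -1.49), with adjusted p = 1.55e-10 and 0.0626 with an estimated correlation. H2-Oa changed by -1.57 ± 0.29. Interferon-stimulated genes fell, 8 of 35 with 1 higher (15 and 1 adjusted over the list alone, median -0.85), with adjusted p = 6.29e-12 and 0.0626 with an estimated correlation. Rtp4 changed by -1.73 ± 0.32, the transcription factor Irf7 by -1.54 ± 0.31 and Usp18, which restrains interferon signalling, by -1.52 ± 0.33. Monocyte genes fell, 6 of 25 with 1 higher (7 and 1 adjusted over the list alone, median -0.48), such as Ms4a6c (-1.40 ± 0.31, 5 of 6 exposed arrays well above background), with adjusted p = 8.75e-04 and 0.275 with an estimated correlation. Platelet genes rose, 20 of 25 (23 adjusted over the list alone, median 1.39), with adjusted p = 8.59e-21 and 0.0626 with an estimated correlation, among them Thbs1 (1.98 ± 0.31) and the platelet tubulin Tubb1 (1.80 ± 0.35). Pf4 was not called (0.89 ± 0.31). For p53 targets, 8 of 24 were higher (10 higher and 1 lower adjusted over the list alone, median 0.40), with adjusted p = 8.75e-04 and 0.129 with an estimated correlation. In an exact two-sided permutation test of list scores, p53 target, B cell, NK, monocyte, eosinophil and basophil, platelet, interferon-stimulated and MHC class II scores did not overlap between the groups (p = 0.0119, the smallest that 84 splits allow, adjusted 0.0342).

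Antioxidant genes rose on day 3, 4 of 28 (7 adjusted over the list alone, median 0.31), with adjusted p = 0.00206 and 0.443 with an estimated correlation. Gclc, for glutathione synthesis, rose by 1.59 ± 0.30. NK genes had a median of 0.55 (2 of 17 higher, 2 adjusted over the list alone; adjusted p = 0.0195, and 0.444 with an estimated correlation). But the call ended without day 3 control replicate 2 (adjusted p = 0.0766) or 3 (0.0784), and the median was -0.11 over probes well above background on all 48 arrays. Ribosomal protein genes had a median of -0.44 with no member called over all genes or adjusted over the list alone (adjusted p = 1.04e-07, and 0.444 with an estimated correlation), and a median of -0.03 with slide as a block. Neutrophil genes had a median of -0.59 with 1 of 27 lower (1 adjusted over the list alone; adjusted p = 0.00181, and 0.444 with an estimated correlation). But that median was 0.10 without day 3 control replicate 2 and 0.59 within the shared slide. The neutrophil receptor gene Trem3 was at least 3.40-fold lower, with 0 of 6 exposed and 2 of 3 control arrays well above background, but its change was 0.70 within the shared slide. Its call ended without day 3 control replicate 1 (adjusted p = 0.26) or 2 (0.0859). Heart and skeletal muscle genes had a median of 1.48 with 1 of 10 higher (5 adjusted over the list alone; adjusted p = 0.0442, and 0.443 with an estimated correlation). The call of that list ended without day 3 control replicate 1 (adjusted p = 0.0766) or 2 (0.0881) or exposed replicate 1 (0.118) or 3 (0.167). Myoglobin (Mb) was at least 2.19-fold higher (adjusted p = 0.0437), a call that 6 of the 9 single arrays ended (adjusted p up to 0.239, without day 3 control replicate 2). The Mdm2 call was ended by 5 (up to 0.13, without day 3 control replicate 1).

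Other genes that rose on day 3 were Arhgap10, at least 2.71-fold, the heat shock gene Hspb1 (2.50 ± 0.30, 1 of 3 control arrays well above background), Ctnnal1 (2.49 ± 0.35, also 1 of 3) and Tal1 (1.57 ± 0.27). The eosinophil gene Ear1 changed by -1.87 ± 0.37. Not called were Bax (0.68 ± 0.27), Trp53inp1 (0.44 ± 0.33), Cd3e (-0.29 ± 0.25), S100a8 (-1.31 ± 0.61), Csf3r (-0.19 ± 0.22 on 5 exposed arrays), Alas2 (-0.19 ± 0.20) and Rps20 (-0.65 ± 0.23). Among lists that camera did not call, T cell genes had a median of 0.11 (2 of 28 higher), eosinophil and basophil genes -0.80 (3 of 13 lower and 1 higher), and reticulocyte genes 0.18 (3 of 32 higher). The others included DNA repair genes at -0.11 (1 higher and 1 lower) and circadian clock genes at 0.37 (1 of 12 higher). Globin transcripts (median -0.07, mean 0.00) and oxidative phosphorylation genes (mean 0.04, with the median at -0.001) held no called member.

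In all, 1308 genes differed on day 3, 1033 higher and 275 lower. The count was 770 without day 3 control replicate 1, 925 with scan day as a block, 896 among the 3 exposed and 3 control arrays of scan day 1, and 511 with slide as a block. Within the shared slide (3 exposed arrays and 1 control), list medians were -1.54 for B cell, -1.46 for MHC class II, 1.77 for platelet, 0.81 for p53 target, 0.60 for NK, 0.58 for antioxidant, -0.34 for monocyte and -0.27 for interferon-stimulated genes, where all genes had 0.10. With slide as a block the day 3 estimates likewise rest on that 1 control array, so neither the gene count nor list tests of that fit can support a call. The median of all genes was 0.03, and was -0.14 with median scaling and -0.12 in the deposited series table. 79.0% of the changed genes were higher, against 61.4% and 56.6% there, 66.9% with quantile scaling and 52.3% with scaling on probes detected on all arrays.

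**Figure D1:**
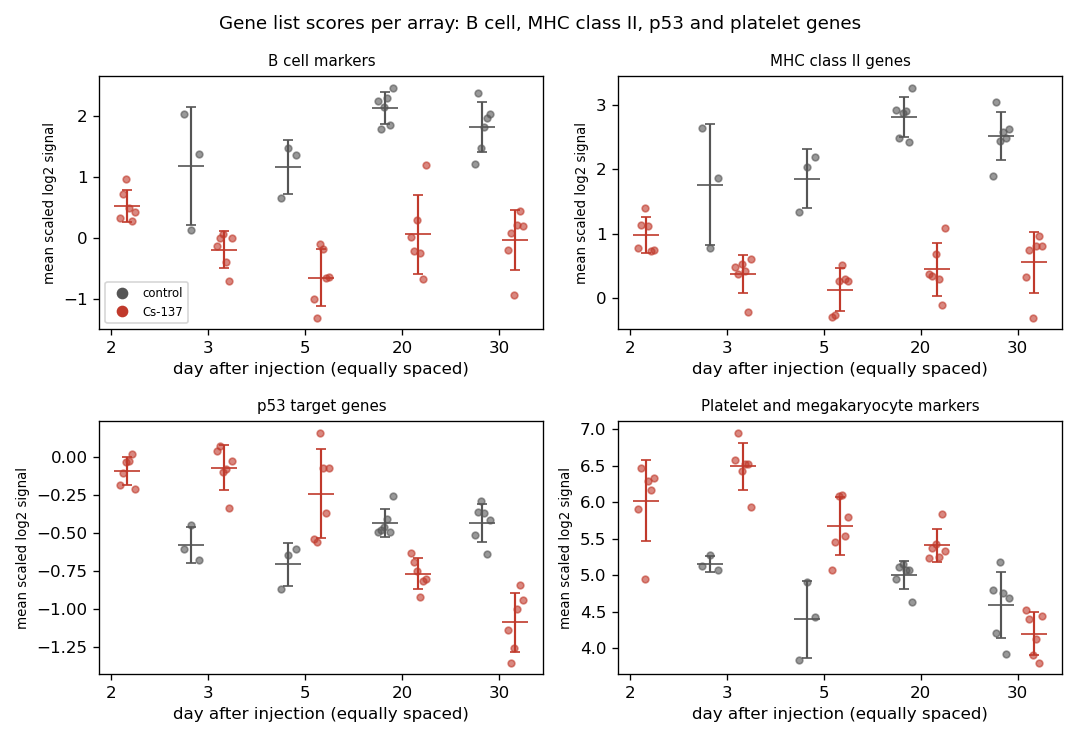
Mean scaled log2 expression of B cell, MHC class II, p53 target and platelet genes on each array by day after injection, where points are arrays, bars are the mean ± SD, grey is control and red is exposed. The labels hold no controls for day 2. The B cell score on day 3 was -0.19 ± 0.30 in 6 exposed and 1.18 ± 0.97 in 3 control arrays, and the platelet score was 6.49 ± 0.33 and 5.15 ± 0.11.

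On day 5, B cell and MHC class II genes were lower and platelet, globin and antioxidant genes higher in 6 exposed than in 3 control arrays, and p53 targets were higher in part. Btla, a lymphocyte inhibitory receptor, changed by -3.47 ± 0.58 with 3 of 6 exposed arrays well above background, Ms4a1 by -3.22 ± 0.65 with 5 of 6, and Cd79b by -2.88 ± 0.60. Bank1 changed by -2.80 ± 0.38 with 3 of 6 and Cd79a by -1.97 ± 0.35. Tnfrsf13c, the BAFF receptor, changed by -3.00 ± 0.59 with 2 of 6 exposed arrays well above background, but by 0.075 with quantile scaling. Phlda3 rose by 2.50 ± 0.26 (adjusted p = 3.68e-08), Cdkn1a by 1.60 ± 0.36 (2 of 3 control arrays well above background), Bax by 1.31 ± 0.27 and Aen by 0.96 ± 0.24, and the p53 target Psrc1 was at least 4.71-fold higher. Mdm2 rose by 0.57 ± 0.21 (adjusted p = 0.0443) and Ccng1 by 1.14 ± 0.36 (adjusted p = 0.0191; 5 of 6 exposed and 2 of 3 control arrays well above background). But 6 and 4 of the 9 single arrays ended these calls when left out (adjusted p up to 0.148 without day 5 control replicate 2, and up to 0.0796 without day 5 control replicate 1). Bbc3 (0.59 ± 0.24) and Trp53inp1 (-0.39 ± 0.33) were not called.

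Of 26 B cell genes, 20 were lower and none higher on day 5 (21 and 1 adjusted over the list alone), with a median of -1.98, adjusted p = 3.83e-13 and 0.181 with an estimated correlation. MHC class II genes fell, 8 of 10 (8 adjusted over the list alone, median -1.88), with adjusted p = 9.88e-08 and 0.181 with an estimated correlation. The invariant chain Cd74 changed by -2.55 ± 0.43 and H2-Ab1 by -2.65 ± 0.47. Platelet genes rose, 20 of 25 (23, with 1 lower, adjusted over the list alone, median 1.27), with adjusted p = 8.70e-12 and 0.324 with an estimated correlation, including Clec1b (1.89 ± 0.30), Pf4 (1.88 ± 0.31) and Ctla2a (2.05 ± 0.32). Exact two-sided permutation tests of these 3 list scores gave p = 0.0119, the smallest that 84 splits allow, with all 6 exposed arrays beyond all 3 controls, and adjusted 0.0913 over the lists. No list passed the exact test after adjustment on day 5. Interferon-stimulated genes fell, 12 of 35 with 1 higher (13 and 1 adjusted over the list alone, median -0.63), with adjusted p = 0.00214 and 0.464 with an estimated correlation. Ifi203 changed by -2.31 ± 0.51 with 4 of 6 exposed arrays well above background and Stat2 by -1.78 ± 0.39 with 3 of 6. Monocyte genes went both ways, 6 of 25 lower and 3 higher (6 and 3 adjusted over the list alone, median -0.59), with adjusted p = 0.0225 and 0.464 with an estimated correlation. The list was not called without day 5 control replicate 3 (adjusted p = 0.155). The protease gene Ctss changed by -2.03 ± 0.43 and the lysozyme gene Lyz2 by 1.41 ± 0.33.

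Reticulocyte genes rose on day 5, 16 of 32 with 1 lower (16 and 1 adjusted over the list alone, median 0.59), with adjusted p = 4.39e-04 and 0.464 with an estimated correlation. List scores of 5 exposed arrays lay above and 1 below all controls (exact p = 0.167). Rhag rose by 1.45 ± 0.30, and Alas2 by 0.74 ± 0.20, though Alas2 was at -0.34 with quantile scaling. Globin transcripts, left after depletion, rose, 4 of 5 (4 adjusted over the list alone, median 1.08), with adjusted p = 0.00101 and 0.324 with an estimated correlation. Hbb-b2 rose by 1.21 ± 0.25. Antioxidant genes rose, 14 of 28 with 1 lower (16 and 1 adjusted over the list alone, median 0.73), such as Gpx4 (2.09 ± 0.34), with adjusted p = 4.14e-06 and 0.324 with an estimated correlation. Oxidative phosphorylation genes rose, 18 of 42 (20 adjusted over the list alone, median 0.39), such as Cox8a (1.22 ± 0.22), with adjusted p = 4.39e-04 and 0.539 with an estimated correlation. But their median was -0.09 with slide as a block. Ribosomal protein genes rose, 15 of 43 (15 adjusted over the list alone, median 0.48), such as Rplp0 (1.43 ± 0.31), with adjusted p = 4.15e-05 and 0.570 with an estimated correlation. But list scores of 4 exposed arrays lay above and 2 below all 3 controls (exact p = 0.381), and the median turned from 0.48 to -0.36 with quantile scaling. For p53 targets, 10 of 24 were higher and 4 lower (11 and 4 adjusted over the list alone, median 0.51), with adjusted p = 0.0142 and 0.375 with an estimated correlation, and adjusted p = 0.0503 without day 5 control replicate 1.

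Further rises on day 5 were those of the actin-binding gene Cnn1 (3.12 ± 0.49, 1 of 3 control arrays well above background), Dusp7 (2.63 ± 0.58) and Cd3e (0.91 ± 0.25), and the lymphocyte homing receptor Ccr7 changed by -1.26 ± 0.32. Csf3r rose by 0.55 ± 0.21 (adjusted p = 0.0477), but was at -0.17 with quantile scaling, and 6 of the 9 single arrays ended the call (adjusted p up to 0.178, without day 5 control replicate 1). Camera did not call T cell genes (median -0.41, 6 of 28 lower and 3 higher), NK genes (0.24, 3 of 17 higher), neutrophil genes (-0.13, 2 of 27 higher), or eosinophil and basophil genes (-0.48, 3 of 13 lower and 1 higher). Inflammatory genes (-0.22, 4 of 23 lower), cell cycle genes (0.15, 7 of 33 higher and 1 lower) and heart genes (1.17, no member called) were not called either. DNA repair genes (median 0.07, mean -0.14), proteasome genes (median -0.01, mean 0.01) and immediate early genes (median 0.09, mean -0.04) had medians and means of opposite sign, and S100a8 was at 0.19 ± 0.61.

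In all, 4756 genes differed on day 5, 2888 higher and 1868 lower. Calls depended on the fit: with the day 5 groups alone in limma 0 genes passed (3176 at an unadjusted p under 0.05, and 22 with the replicate number as a block in that fit). With a normexp background 1 gene passed, and with slide as a block 2051. The count was 2876 without day 5 control replicate 2, 2291 without control replicate 3 and 2969 without exposed replicate 6. Within the shared slide (2 exposed and 2 control arrays), list medians were -3.09 for B cell, -2.59 for MHC class II, -1.17 for T cell, -0.92 for interferon-stimulated, 0.40 for platelet, 0.88 for globin, 0.31 for reticulocyte, 0.27 for antioxidant and 0.19 for p53 target genes, where all genes had 0.20. With slide as a block, adjusted p was 2.56e-17 for B cell, 2.40e-10 for MHC class II, 0.00914 for platelet and 0.818 for p53 target genes. The median of all genes was -0.01, and was -0.15 with quantile scaling, -0.29 in the deposited series table and -0.25 with scaling on probes detected on all arrays. 60.7% of the changed genes were higher, against 42.8%, 24.3% and 37.7% there.

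On day 20, B cell, T cell, neutrophil, monocyte, interferon-stimulated, inflammatory, MHC class II and proteasome genes were lower, and reticulocyte genes higher, in 6 exposed than in 6 control arrays. Cd55, a complement regulator, changed by -3.73 ± 0.46 with 2 of 6 exposed arrays well above background, Fcrla by -3.48 ± 0.40 with 3 of 6, and Bank1 by -3.24 ± 0.31 with 3 of 6. Ms4a1 changed by -2.70 ± 0.53 with 5 of 6 and Cd79a by -2.46 ± 0.29, and the co-stimulatory ligand Icosl was at least 7.05-fold lower. Metallothionein 1 (Mt1) rose by 1.97 ± 0.18 (adjusted p = 9.76e-11), Atf5 by 2.03 ± 0.30 and Hspb1 by 1.94 ± 0.24 (4 of 6 control arrays). The p53 targets went both ways (all genes had a median of 0.54). Btg2 changed by -2.30 ± 0.27 with 3 of 6 exposed arrays, Sesn1 by -2.16 ± 0.27 with 4 of 6, Trp53inp1 by -1.45 ± 0.27 with 5 of 6, Aen by -0.73 ± 0.20 with 4 of 6 and Bbc3 by -0.70 ± 0.20. Phlda3 rose by 0.69 ± 0.21, and no fold is given for Cdkn1a (well above background on 1 exposed array, no control). Mdm2 (-0.17 ± 0.18), Bax (-0.37 ± 0.22), Ccng1 (-0.26 ± 0.30) and Pf4 (0.37 ± 0.25) were not called.

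Of 26 B cell genes, 21 were lower and 1 higher on day 20 (21 and 1 adjusted over the list alone), with a median of -2.45, adjusted p = 3.75e-10 and 0.250 with an estimated correlation. MHC class II genes fell, 10 of 10 (10 adjusted over the list alone, median -2.30), with adjusted p = 5.29e-08 and 0.139 with an estimated correlation. H2-Aa changed by -3.15 ± 0.34 with 5 of 6 exposed arrays well above background and Cd74 by -2.98 ± 0.35. T cell genes fell, 19 of 28 with 7 higher (19 and 7 adjusted over the list alone, median -1.10), with adjusted p = 0.00121 and 0.303 with an estimated correlation. Ccr7 changed by -2.66 ± 0.26 and the adhesion receptor Cd2 by -2.19 ± 0.34. Cd3e was among the higher members (0.48 ± 0.20, adjusted p = 0.0324), but was at -0.028 in the deposited series table. Its call ended in 4 of 12 cases when single arrays were left out (adjusted p up to 0.0689, without exposed replicate 2). Neutrophil genes fell, 17 of 27 with 2 higher (17 and 2 adjusted over the list alone, median -1.07), with adjusted p = 1.23e-04 and 0.339 with an estimated correlation. Retnlg changed by -2.80 ± 0.40, the calcium-binding S100a8 by -2.23 ± 0.50, and the gelatinase Mmp9 was at least 2.10-fold lower. Csf3r changed by -0.40 ± 0.17 (adjusted p = 0.0351), a call that 6 of the 12 single arrays ended (adjusted p up to 0.0716, without exposed replicate 3). Elane, the elastase of granulocyte precursors, rose by 1.19 ± 0.15, while primary granule genes together had a median of 0.07 and a mean of -0.03 (4 of 10 higher and 2 lower).

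Monocyte genes fell on day 20, 14 of 25 with 4 higher (14 and 4 adjusted over the list alone, median -0.59), with adjusted p = 0.00333 and 0.303 with an estimated correlation. The chemokine receptor Ccr2 changed by -2.38 ± 0.37 with 1 of 6 exposed arrays well above background. Interferon-stimulated genes fell, 20 of 35 with 4 higher (20 and 4 adjusted over the list alone, median -0.70), with adjusted p = 4.49e-05 and 0.303 with an estimated correlation. Ifit3 changed by -2.31 ± 0.25 with 2 of 6 exposed arrays well above background and Irf9 by -1.63 ± 0.20. Inflammatory genes fell, 17 of 23 with 4 higher (17 and 4 adjusted over the list alone, median -1.24), with adjusted p = 1.72e-04 and 0.139 with an estimated correlation. The cytokine signalling inhibitor Socs3 changed by -2.12 ± 0.30 with 3 of 6 exposed arrays well above background, and Relb rose by 1.25 ± 0.13 at its brightest probe but was at -0.35 as the mean of its probes. Proteasome genes fell, 23 of 31 with 2 higher (23 and 2 adjusted over the list alone, median -0.79), such as Psma7 (-1.45 ± 0.23), with adjusted p = 1.05e-06 and 0.303 with an estimated correlation. Ribosomal protein genes fell, 19 of 43 with 7 higher (18 and 7 adjusted over the list alone, median -0.39), such as Rpl14 (-2.05 ± 0.33), with adjusted p = 0.0120 and 0.688 with an estimated correlation. Oxidative phosphorylation genes fell, 18 of 42 with 10 higher (18 and 10 adjusted over the list alone, median -0.25), with adjusted p = 0.0163 and 0.633 with an estimated correlation. For p53 targets, 10 of 24 were lower and 5 higher (10 and 5 adjusted over the list alone, median -0.44), with adjusted p = 0.0284 and 0.303 with an estimated correlation. Reticulocyte genes rose, 25 of 32 (25 adjusted over the list alone, median 0.75), with adjusted p = 0.0163 and 0.565 with an estimated correlation. Alas2 rose by 0.96 ± 0.16 and the ferrochelatase Fech by 0.84 ± 0.17, though Fech was at -0.10 with quantile scaling.

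Eosinophil and basophil genes fell on day 20, 6 of 13 with 1 higher (6 and 1 adjusted over the list alone, median -0.54), with adjusted p = 0.0491 and 0.303 with an estimated correlation. But 8 of the 12 single arrays ended the call (control replicates 1 to 4 and exposed replicates 2 to 5, adjusted p from 0.0501 to 0.0697). Immediate early genes fell, 7 of 12 with 3 higher (7 and 3 adjusted over the list alone, median -0.94), with adjusted p = 0.0455 and 0.303 with an estimated correlation. But control replicates 2 and 5 and exposed replicates 2, 3 and 5 each ended the call (adjusted p from 0.0501 to 0.0731). Camera did not call cell cycle genes (median 0.70, all genes 0.54, 21 of 33 higher and 6 lower), globin transcripts (0.93, 5 of 5 higher), heart genes (1.23, 8 of 10 higher, 9 adjusted over the list alone), antioxidant genes (0.40, 13 of 28 higher and 4 lower) or platelet genes (0.40, 5 of 25 higher). Nor did it call circadian clock genes (-0.37, 5 of 12 lower and 2 higher), DNA repair genes (-0.06, 8 of 24 higher and 8 lower) or NK genes (median 0.04, mean -0.16, 4 of 17 higher and 5 lower). Among their members, the nucleotide synthesis gene Tyms rose by 1.65 ± 0.18, the heart muscle gene Myl3 by 1.13 ± 0.18, and Hba-a1 by 0.93 ± 0.20 (-0.044 with quantile scaling).

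In all, 13217 genes differed on day 20, 8643 higher and 4574 lower. The median of all genes was 0.54, and was 0.24 with median and 0.16 with quantile scaling, 0.05 in the deposited series table and 0.32 with scaling on probes detected on all arrays. 65.4% of the changed genes were higher, against 52.0% with median and 51.9% with quantile scaling and 45.4% in the series table, so this split depended on the scaling. Within the shared slide (2 exposed and 2 control arrays), list medians were -2.62 for B cell, -2.64 for MHC class II, -1.35 for T cell, -1.0 for neutrophil and -0.48 for monocyte genes. They were -0.48 for interferon-stimulated, -0.64 for proteasome, 0.92 for reticulocyte and -0.33 for p53 target genes, where all genes had 0.52. With slide as a block, adjusted p was 6.83e-10 for B cell, 0.00504 for T cell, 3.03e-04 for proteasome, 0.0481 for p53 target, 0.0948 for ribosomal and 0.155 for oxidative phosphorylation genes. Exact two-sided permutation tests, against no change, found 20 of 23 list scores to differ (smallest p = 0.00216, adjusted 0.00383, n = 6 against 6). As most genes changed, this does not set lists apart.

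On day 30, B cell, T cell, monocyte, interferon-stimulated, inflammatory, MHC class II, ribosomal protein, oxidative phosphorylation and proteasome genes were lower in 6 exposed than in 6 control arrays. Bank1 changed by -2.43 ± 0.31 with 4 of 6 exposed arrays well above background, Cd55 by -3.19 ± 0.46 with 3 of 6, Ms4a1 by -2.67 ± 0.53 and Cd79a by -1.81 ± 0.29. The interleukin 7 receptor gene Il7r was at least 4.48-fold lower, the adhesion adaptor gene Lpxn at least 5.37-fold and the nucleoside transporter gene Slc28a2 at least 2.98-fold, each with no exposed array well above background. Trub2 changed by -3.52 ± 0.37 with 2 of 6. Many p53 targets were lower. Bax changed by -1.56 ± 0.22, Aen by -1.45 ± 0.20, Bbc3 by -1.17 ± 0.20 and Trp53inp1 by -1.59 ± 0.27, each with 5 of 6 exposed arrays well above background. Mdm2 changed by -1.24 ± 0.18, Rps27l by -1.71 ± 0.24 and the histone gene H2ax by -1.05 ± 0.15, and Ccng1 and the cell death gene Pmaip1 were each at least 1.53-fold lower (5 of 6 control arrays well above background for Ccng1). Cdkn1a rose by 1.16 ± 0.29 (adjusted p = 6.66e-04; 5 of 6 exposed and 3 of 6 control arrays well above background), as did Mesp2 by 2.46 ± 0.22, Tgif2 by 2.22 ± 0.23 and Mt1 by 1.77 ± 0.18. Phlda3 (-0.27 ± 0.21), Cd3e (0.35 ± 0.20) and Pf4 (-0.42 ± 0.25) were not called.

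Proteasome genes fell, 27 of 31 (27 adjusted over the list alone), with a median of -1.47, adjusted p = 1.23e-10 and 0.350 with an estimated correlation. Psma7 changed by -2.18 ± 0.23. Ribosomal protein genes fell, 34 of 43 with 1 higher (34 and 1 adjusted over the list alone), with a median of -1.18, adjusted p = 3.56e-09 and 0.496 with an estimated correlation. Rpl14 changed by -2.70 ± 0.33 and Rps4x by -2.13 ± 0.25. Oxidative phosphorylation genes fell, 30 of 42 (30 adjusted over the list alone), with a median of -0.94, adjusted p = 1.02e-07 and 0.412 with an estimated correlation. The succinate dehydrogenase subunit Sdhb changed by -1.84 ± 0.20. B cell genes fell, 23 of 26 with 1 higher (23 and 1 adjusted over the list alone), with a median of -2.19, adjusted p = 1.72e-07 and 0.350 with an estimated correlation. MHC class II genes fell, 9 of 10 (9 adjusted over the list alone, median -2.16), with adjusted p = 3.26e-05 and 0.350 with an estimated correlation. H2-DMb1 changed by -2.69 ± 0.30. T cell genes fell, 17 of 28 with 5 higher (18 and 6 adjusted over the list alone, median -1.24), with adjusted p = 0.00594 and 0.496 with an estimated correlation. Ccr7 changed by -1.86 ± 0.26. Interferon-stimulated genes fell, 20 of 35 with 2 higher (20 and 2 adjusted over the list alone, median -0.85), such as Irf9 (-1.70 ± 0.20, 5 of 6 exposed arrays well above background), with adjusted p = 2.24e-04 and 0.412 with an estimated correlation. Inflammatory genes fell, 15 of 23 with 3 higher (15 and 3 adjusted over the list alone, median -0.71), such as Nfkbia, the NF-kB inhibitor (-1.70 ± 0.26), with adjusted p = 0.00546 and 0.350 with an estimated correlation. Monocyte genes fell, 12 of 25 with 2 higher (12 and 2 adjusted over the list alone, median -0.55), with adjusted p = 0.00546 and 0.412 with an estimated correlation. Ccr2 changed by -3.22 ± 0.37 with 1 of 6 exposed arrays well above background and Ly6c1 by -2.52 ± 0.32. For p53 targets, 13 of 24 were lower and 4 higher (13 and 5 adjusted over the list alone, median -0.71), with adjusted p = 0.00546 and 0.350 with an estimated correlation.

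Camera did not call NK genes on day 30 (median -0.98, 8 of 17 lower and 2 higher) or neutrophil genes (-0.86, 14 of 27 lower and 4 higher). Of their members, the chemokine gene Ccl5 changed by -1.90 ± 0.29 and the granzyme gene Gzma by -1.67 ± 0.30. Cxcr2 changed by -1.84 ± 0.43 with 5 of 6 exposed arrays well above background, S100a8 by -1.61 ± 0.50 and Csf3r by -0.66 ± 0.17. Reticulocyte genes (0.40, all genes 0.39, 8 of 32 higher and 1 lower) were not called, though Alas2 rose by 0.54 ± 0.16. The same held for globin transcripts (0.54, 4 of 5 higher), platelet genes (-0.47, 9 of 25 lower and 2 higher), antioxidant genes (-0.24, 11 of 28 lower and 4 higher) and cell cycle genes (0.18, 8 of 33 higher and 5 lower). Also not called were DNA repair genes (-0.06, 6 of 24 higher and 8 lower), heart genes (0.95, 5 of 10 higher, 3 adjusted over the list alone), immediate early genes (-0.40, 5 of 12 lower and 2 higher), and eosinophil and basophil genes (-0.55, 6 of 13 lower and 1 higher). Primary granule genes (median 0.16, mean -0.12) and circadian clock genes (median 0.06, mean -0.25) had medians and means of opposite sign.

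In all, 12284 genes differed on day 30, 6980 higher and 5304 lower, and 7858 with slide as a block. The median of all genes was 0.39, and was 0.18 with median and 0.31 with quantile scaling, -0.06 in the deposited series table and 0.33 with scaling on probes detected on all arrays. 56.8% of the changed genes were higher, against 45.0% with median scaling and 41.9% in the series table. Within the shared slide (2 exposed and 2 control arrays), list medians were -2.46 for B cell, -2.27 for MHC class II, -1.16 for T cell, -0.66 for interferon-stimulated, -1.48 for proteasome and -0.65 for p53 target genes, where all genes had 0.46. All 10 lists called on day 30 stayed called with slide as a block, at adjusted p of 1.25e-07 for ribosomal, 1.78e-07 for oxidative phosphorylation and 1.97e-11 for proteasome genes. Exact two-sided permutation tests, also against no change, found 19 of 23 list scores to differ (n = 6 against 6, smallest adjusted p = 0.00332).

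**Figure D2:**
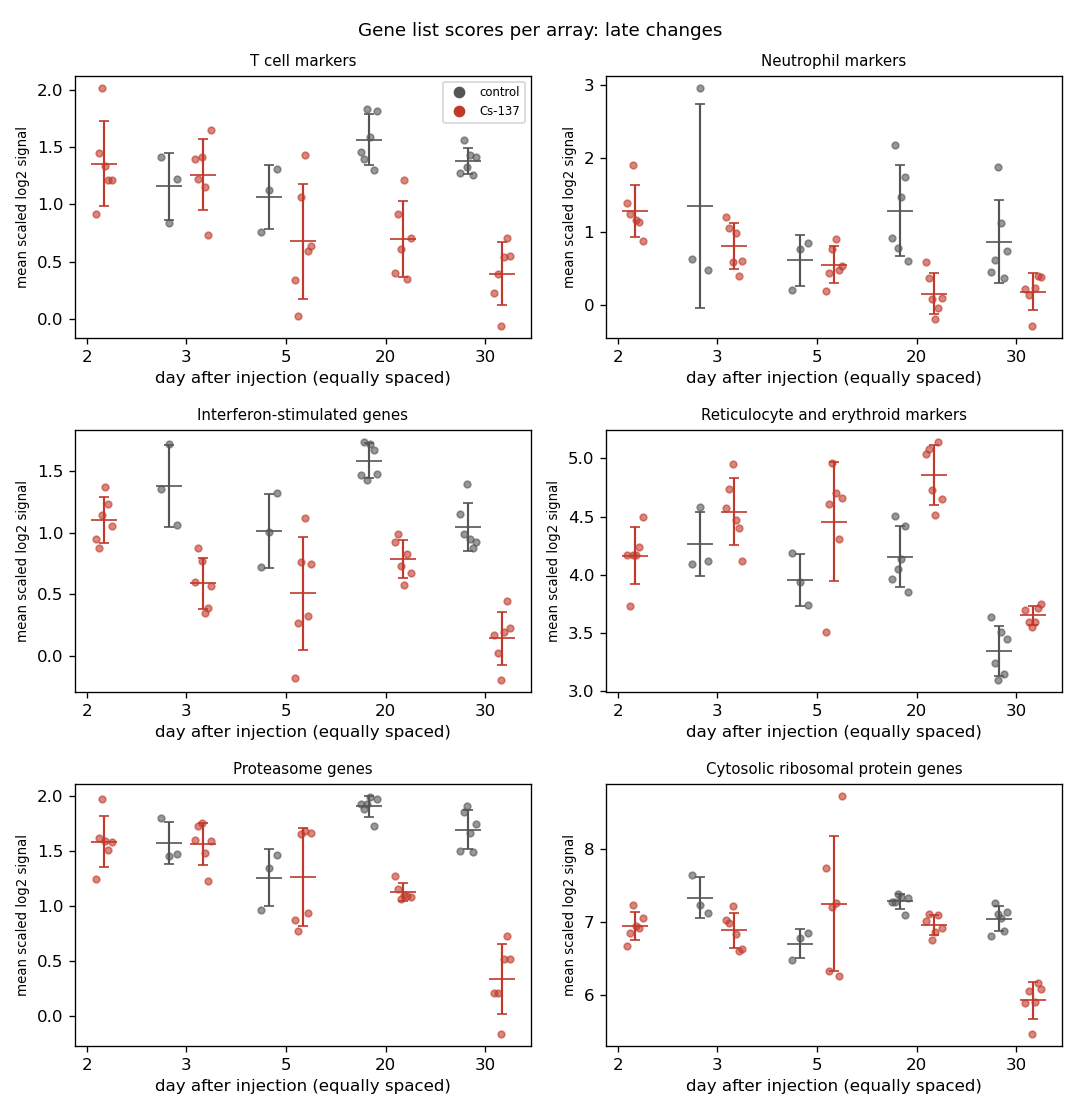
Mean scaled log2 expression of T cell, neutrophil, interferon-stimulated, reticulocyte, proteasome and ribosomal protein genes on each array by day after injection, where points are arrays, bars are the mean ± SD, grey is control and red is exposed. On day 30 the median change of ribosomal protein genes was -1.18 and that of proteasome genes -1.47.

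Changes of the response between days were tested directly. Between days 3 and 5 together and days 20 and 30 together, the response of 11250 genes differed, 55.2% of them upward (47.6% with median scaling). The response of p53 targets differed by a median of -1.20 (adjusted p = 1.80e-05, and 0.156 with an estimated correlation). Platelet genes differed by -1.45 (adjusted p = 7.77e-08, and 0.546 with an estimated correlation) and proteasome genes by -1.19 (adjusted p = 5.90e-09, and 0.546 with an estimated correlation). Il7r (adjusted p = 7.51e-05) and alpha-fetoprotein (Afp) differed downward, with no exposed array well above background on days 20 and 30, so no size is given. From day 20 to day 30 the response of 238 genes differed, 83 upward and 155 downward (30 and 0 with median scaling). With slide as a block the count was 5. It was 37, 137, 77, 132, 54 and 34 without day 20 control replicates 1 to 6, and 44, 65 and 47 without exposed day 20 replicates 1, 2 and 5. It was 60, 40, 46, 419 and 44 without day 30 control replicates 2 to 6, and 132, 129, 33 and 72 without exposed day 30 replicates 1 to 4. Between day 3 and day 5 the response of 2713 genes differed, with 113 under a slide block and 14 under a scan day block. Of them 58.6% differed upward, against 47.8% with quantile scaling and 32.5% in the deposited series table. The count was 1025 and 1111 without day 3 control replicates 1 and 2, and 1806 and 1472 without exposed day 3 replicates 4 and 6. It was 1589, 1555 and 1255 without day 5 control replicates 1 to 3, and 4356 and 1590 without exposed day 5 replicates 2 and 6.

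Genes that changed the same way on at least 2 of the 5 days numbered 12176. On all 5 days 7 genes were higher, among them Epor (1.09, 0.96, 0.84, 0.75 and 0.44 on days 2, 3, 5, 20 and 30), Psrc1 and Cdkn1a. On day 20 neither Psrc1 nor Cdkn1a had a control array well above background, and Cdkn1a had 1 exposed array; its day 2 call ended in 7 of 12 cases as above. Lower on all 5 days were 19 genes, among them Cd79a, the inhibitory Fc receptor Fcgr2b, Fcrla (-1.16, -2.96, -2.96, -3.48 and -2.64), the MHC class II genes H2-DMb2 and H2-Ob, and Spns2. These counts depended on the scaling. With median scaling 1 of the 7 and 2 of the 19 stayed, of those named only Cdkn1a and Spns2. With quantile scaling 4 and 7 stayed, of those named only Epor, Cd79a, H2-Ob and Spns2. Days 20 and 30 shared 6321 higher and 3925 lower genes, where independent lists of these sizes would share 3331 and 1340. Days 3 and 5, which have separate controls, shared 492 higher and 124 lower genes, where independent lists would share 165 and 28.4. Days 3 and 20 shared 187 higher genes, where independent lists would share 493, and 202 lower genes, where they would share 69.5. Day 2 against the day 5 controls alone shared 732 higher genes with day 3, where independent lists would share 165, and 25 lower, where they would share 57.3. Day 2 against the day 3 controls alone shared 55 higher genes with day 5 and 1 lower, where independent lists would share 15.6 and 2.17.

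**Figure D3:**
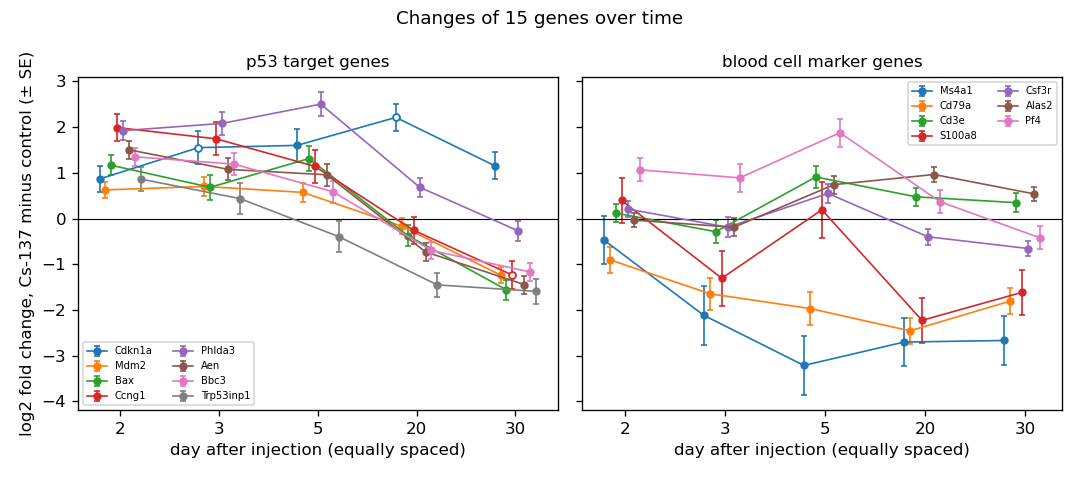
Log2 fold change of 8 p53 target genes and 7 blood cell marker genes on each day against control, where points are estimates (open where a group had no array well above background) and bars ± SE; day 2 was set against the mean of the day 3 and day 5 controls. Phlda3 was at 1.92, 2.08, 2.50, 0.69 and -0.27 on days 2, 3, 5, 20 and 30.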

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

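Tests chosen only after the results were seen were those of scaling, dim probes, paired splits and carried-over heart tissue, the list tests of the contrasts between days, the scan day block and the day 3 comparison within scan day 1.

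Single arrays stood apart from the other 5 of their group in 26 of 428 groups of values that were tested with Dixon's criterion. Chance flags about 1 in 20 groups. Exposed day 2 replicate 3 accounted for 4 of them, with NK genes at 2.28, primary granule genes at 0.46, platelet genes at 4.95 and Pf4 at 9.08 (scaled log2 expression), and Spns2 in exposed day 2 replicate 2 was at -2.10. Exposed day 3 replicate 5 had MHC class II genes at -0.21, Bax at 1.65 and Bbc3 at 0.98, and exposed day 3 replicate 6 had Pf4 at 9.79. Exposed day 5 replicate 5 had Cdkn1a at 0.042. On day 20, control replicate 6 had p53 targets at -0.26 and Bax at 1.79, and control replicate 5 had primary granule genes at -0.94. Of the exposed day 20 arrays, replicate 5 had platelet genes at 5.85 and Btg2 at -2.05, replicate 6 had heart genes at 0.23, and replicate 1 had Cdkn1a at -0.22. On day 30, control replicate 3 had inflammatory genes at 0.76, Cxcr2 at 2.34 and Ccr2 at 2.03, and control replicate 1 had Trub2 at 0.46 and H2-DMb1 at 2.44. Also on day 30, control replicate 2 had Tgif2 at 0.34, control replicate 5 had H2ax at 1.07, exposed replicate 2 had Slc28a2 at -2.73, and exposed replicate 5 had Rps27l at 0.55.

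The response differed between days in 11250 genes for days 20 and 30 against days 3 and 5, 2713 for day 5 against day 3 and 238 for day 30 against day 20 (limma contrasts of the differences). Of the genes below, all but Tmem97, Bhlha15, Cxcr6 and Klrb1a had a group with no array well above background, so their values are fitted and not sizes. From the early to the late days, Grm7 differed by 2.74 ± 0.57 and Ces3b by 2.58 ± 0.32, and Mtln by -3.16 ± 0.61, Il7r by -2.86 ± 0.58 and Afp by -2.75 ± 0.38. Between day 3 and day 5, Pabpc6 differed by 4.73 ± 1.32, Sohlh1 by 4.16 ± 0.67 and Mex3a by 3.87 ± 1.0, and Tmem97 by -3.58 ± 0.69 and Bhlha15 by -3.51 ± 0.88. Without day 3 control replicate 1 the calls of Pabpc6 (adjusted p = 0.105), Mex3a (0.0666) and Bhlha15 (0.0566) ended. Between day 20 and day 30, Ifit3b differed by 2.15 ± 0.43, Mmp9 by 1.98 ± 0.48, Hif1a by 1.78 ± 0.46 and Cybb by 1.68 ± 0.31. Cxcr6 differed by -3.22 ± 0.75, Id2 by -2.81 ± 0.60, Klrb1a by -2.02 ± 0.52 and Scd2 by -1.80 ± 0.46. Of these, Mmp9, Hif1a, Cxcr6, Klrb1a and Scd2 were not called without 11, 17, 8, 18 and 16 of the 24 single arrays, at adjusted p up to 0.0748, 0.0782, 0.0712, 0.0992 and 0.0927, in each case without exposed day 30 replicate 3.

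Among lists, the late response was below the early one by a median of -1.20 for p53 targets, -1.10 for T cell, -1.49 for NK, -1.45 for platelet, -0.71 for inflammatory, -0.59 for antioxidant, -0.76 for ribosomal protein, -0.99 for oxidative phosphorylation and -1.19 for proteasome genes. From day 3 to day 5 it rose by 1.09 for globin transcripts, 0.98 for ribosomal protein and 0.49 for oxidative phosphorylation genes. From day 20 to day 30 it differed by 0.12 for B cell, 0.47 for neutrophil and 0.28 for MHC class II genes. The difference was -0.45 for NK, -0.41 for reticulocyte, -0.85 for platelet, -0.56 for antioxidant, -0.83 for ribosomal protein, -0.78 for oxidative phosphorylation and -0.59 for proteasome genes. None of these 22 differences passed with an estimated correlation, where adjusted p was at least 0.156, 0.999 and 0.428 in the 3 contrasts.

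Other splits of the same arrays were counted for each result. Chance could be excluded for day 20 (1 of 100 splits gave as many genes: real 13217, highest other 8815). The same held for day 30 (1 of 100: 12284 and 9172). The splits treat arrays as exchangeable, but groups of days 20 and 30 shared 1 slide each day. Control groups (1 of 100: 12093 and 4436) had a scan day each, so scan day stays open. Nor can the day 2 share (1 of 100: 2674 and 2431) exclude chance, as replicate numbers were correlated and scan days differed. Only 14 splits parted as many pairs (3, highest other 1685), too few for a share under 0.05. The day 2 count was 404 with scan day and 408 with the replicate number as a block. Chance could also be excluded by share for day 3 (2 of 84; real 1308, highest other 2962), but that other split sets the 3 exposed arrays of scan day 2 against the rest. Within scan day 1 the real count was 896, and with scan day as a block 925. For day 5 it was 3 of 84 (real 4756), and exposed replicates 3, 4 and 6 against the rest gave 8262, which points to a structure among the exposed arrays. For late against early it was 1 of 100 (11250 and 8834). It was 2 of 100 for day 5 against day 3 (2713 and 4104) and for day 30 against day 20 (238 and 6986). Splits also move changes within days, so these 3 shares cannot exclude chance. The number of lists called by camera was not beyond that of other splits on day 2 (90 of 100 gave as many; real 6, highest other 16), day 3 (13 of 84; 11 and 16), day 5 (9 of 84; 11 and 13) and day 30 (47 of 100; 10 and 14). On day 20 chance could be excluded (3 of 100; 14 and 14).

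Of changed genes, 65.4% were higher on day 20 and 56.8% on day 30. Dim probes stayed open as part of this excess. On day 20, 61.2% were higher among 10050 genes well above background on all 12 control arrays of the other days. It was 71.1% among the others and 77.6% with no filter. Scaling went with the excess: 51.9% were higher on day 20 with quantile scaling. Of the 584 receptor genes below, 497 were higher and 0 lower there. Camera set lists against such genes and called 13 of 14 lower (10 of 10 on day 30). Higher late calls may thus come in part from scaling. An uneven change after exposure was not tested.

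The day 2 count may hold differences between the control groups. The 2 groups were read on different scan days, and 981 of the genes changed on day 2 also differed between them, where independent lists would share 585, a ratio of 1.68. In 973 of the 981 the day 2 change was opposite in sign to the difference of day 5 from day 3 controls. Against the day 3 controls alone, of the same scan day as the day 2 arrays, list medians were 0.769 of their size for p53 target, 0.678 for platelet and 0.718 for NK genes (0.44, 0.94 and 0.67 in place of 0.57, 1.38 and 0.94). That argues against a scan day difference as the whole cause of these medians. But 5, 2 and 1 of their members were called higher in place of 11, 23 and 10, since changes were smaller and the median SE was 0.33, 0.33 and 0.36 in place of 0.27, 0.26 and 0.29. Age and day of sampling of the controls stayed open, and were not tested.

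Heart and skeletal muscle genes had medians of 1.48, 1.17, 1.23 and 0.95 on days 3, 5, 20 and 30 and -0.13 on day 2. Receptor genes (below) had 1.19 and 0.98 on days 20 and 30, so a shift of dim probes stays open there. Blood came from the heart, and carried-over tissue could raise heart genes together. With group means taken out, the 10 members had a median correlation across arrays of 0.238. That lies between bounds set for and against (0.5 and 0.2), so the source stays open. Single arrays held some of these genes high together. On exposed day 3, replicates 1 and 3 had Myh6 at 2.23 and 3.46, Myl2 at 1.52 and 2.67, Tnnt2 at 0.04 and 0.45 and Mb at 0.56 and 1.25, where the other 4 arrays were at most at 0.27, -0.56, -2.36 and -1.53. But Myh7 (-1.33 and -1.13), Acta1 (-1.15 and -1.13) and Nppa (-0.96 and -1.01) did not stand out there. On exposed day 5, replicates 1 and 3 had Myh6 at 1.95 and 3.38 and Mb at 0.65 and 0.94 (others at most 0.56 and -1.67). On exposed day 20 replicate 6 had 1.81 and 0.13 (others at most 0.03 and -2.60), but the lowest Myh7 (-2.18). On day 30 none stood out in Myh6 (exposed 0.31 to 0.71). The 6 brightest of a wider set, tested earlier, gave 0.422. Random sets of as many genes reached 0.113 at the 95th percentile, and no biological cause was tested.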

How the results depend on the processing

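Alternatives chosen only after the results were seen were scan day as a block, scaling on probes detected on all arrays, leaving out 3 doubtful arrays (exposed day 5 replicates 5 and 6 and exposed day 30 replicate 2), genes detected on every compared array, and scan day 1 alone. Unless a reason is given, the cause was not tested.

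Outlier spots kept, an intensity trend and a gene's probes averaged moved none of the counts below by more than 1.5 times, and all 18 controls, run for day 2 only, gave 3799 there. Counts moved beyond that are given for days 2, 3, 5, 20 and 30, then for contrasts between days, control differences and genes shared by at least 2 days. A normexp background gave 1082, 631 and 1 (2655 at an unadjusted p under 0.05) on days 2, 3 and 5, and 8739 on day 20. It gave 0 and 0 for the contrasts of day 5 with day 3 and day 30 with day 20 in limma (2286 and 791 unadjusted), 4356 among controls and 7505 shared genes. Probes well above background on all 48 arrays gave 1243, 771, 2855, 4933 and 4993, then 4674 late against early, 461 for day 30 against day 20, 4883 among controls and 5189 shared, with 6506 genes tested. Genes detected on every compared array gave 1608 on day 2, 5579 on day 20, 6574 on day 30 and 5111 shared, also with fewer genes tested. No filter gave 20324 on day 20, where more genes were tested, and 31 for day 30 against day 20. The deposited series table gave 6527 on day 20, 7306 on day 30, 126 for day 30 against day 20, 6959 among controls and 7131 shared.

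Slide as a fixed block gave 10, 511, 2051 and 7858 on days 2, 3, 5 and 30, 4694 late against early, 113 for day 5 against day 3, 5 for day 30 against day 20 and 6395 shared. Slides that hold 1 group only do not inform it, and on day 3, and in part on day 2, it rests on 1 control array. Slide as a random block (consensus correlation 0.121) gave 1647 on day 2, 182 for day 5 against day 3 and 10 for day 30 against day 20. Scan day as a block gave 404 on day 2 and 14 for day 5 against day 3. Only the groups compared gave 3880, 963 and 0 (3176 unadjusted) on days 2, 3 and 5, 0 for day 5 against day 3 (3193 unadjusted) and 2099 for day 30 against day 20. The replicate number as a block in that same fit gave 408, 171 and 22, 0 (2287 unadjusted) and 1677, so on day 5 and in these contrasts the restricted fit had already moved the count. Residuals of exposed and control arrays of the same replicate number correlated above 0.1 in 3 of 3 pairs between day 2 and the day 5 controls and 0 of 3 between day 2 and the day 3 controls. They did in 1 of 3 on day 3, 2 of 3 on day 5, 3 of 6 on day 20 and 2 of 6 on day 30.

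The day 3 controls alone gave 119 on day 2, and the day 5 controls alone 6671. Both early control groups together gave 2007 on day 3. Median scaling gave 580 on day 3, 1721 for day 5 against day 3 and 30 for day 30 against day 20. Quantile scaling gave 734 for the last of these, array weights 2961 for it and 5161 on day 2. Without the 3 doubtful arrays, day 5 had 2879, day 5 against day 3 had 1762 and day 30 against day 20 had 819. At other thresholds, an unadjusted p under 0.001 gave 1324, 852, 2047, 8748 and 7850. An adjusted p of 0.05 with a fold of at least 2 gave 1469, 2784, 8359 and 6972 on days 2, 5, 20 and 30. And an adjusted p of 0.01 gave 1122, 641 and 2157 on days 2, 3 and 5. Camera called 52 list tests, and 0 with an estimated correlation. Ranks called 56 (50 of the 52) and fry, against no change, 61 (44 of the 52). Probes well above background on all 48 arrays ended 18 of the 52 list calls and added 7. Slide as a block ended 11 and added 6.

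With 1 array left out, counts ran from 1615 to 2896 on day 2, 770 to 1354 on day 3, 2291 to 6245 on day 5, 12381 to 13124 on day 20 and 11190 to 12321 on day 30. They ran from 10009 to 11779 late against early, 1025 to 4356 for day 5 against day 3, and 33 to 419 for day 30 against day 20. They ran from 10090 to 12038 among controls, 50 to 54 for list calls and 11541 to 12736 for shared genes.

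Directions turned as follows. With quantile scaling, Csf3r on day 5 was at -0.17, Alas2 at -0.34, Tnfrsf13c at 0.075 and ribosomal protein genes at -0.36, and on day 20 Fech was at -0.10 and Hba-a1 at -0.044. Probes well above background on all 48 arrays put Tnfrsf13c on day 5 at 0.11 and NK genes on day 3 at -0.11. The series table put Cd3e on day 20 at -0.028, and the mean of its probes put Relb on day 20 at -0.35. Slide as a block put Trem3 at 0.70 and neutrophil genes at 0.59 on day 3, as did the values within slide 3. It put oxidative phosphorylation genes at 0.43 on day 3 and -0.092 on day 5, the latter as within slide 5. It put neutrophil genes on day 2 at -0.55, proteasome genes on day 5 at -0.46, and the differences of Tmem97 and Bhlha15 between days 3 and 5 at 0.047 and 0.42. Oxidative phosphorylation genes on day 3, at a median of about 0, were at 0.26 with normexp, 0.26 with both early control groups, and 0.19 with the replicate block, the scan day block and scan day 1 alone. On day 2 they were at -0.15 with the day 3 controls alone. Neutrophil genes on day 3 were at 0.10 without day 3 control replicate 2, the highest with 1 array left out, and at -1.03 without replicate 3, the lowest.

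Of the genes named as changed, slide as a block ended the calls of 25 of 26 on day 2, 14 of 28 on day 3 (and turned 1 more, Trem3), 9 of 33 on day 5, 4 of 38 on day 20 and 4 of 37 on day 30. On day 2 the fit of only the groups compared ended 1 call. The calls of 32 of the 33 on day 5 ended with normexp, and of all 33 with the day 5 groups alone. The 5 genes named for the late against early contrast kept their calls where they had a value (1 gene in the series table). Of the 5 named for day 5 against day 3, the slide block ended 3 calls and turned 2, and normexp and only the groups compared ended all 5. Of the 8 named for day 30 against day 20, the slide block and normexp ended all 8 and median scaling 6. On the dimmest array 27.2% of probes were well above background, and values of genes at background in a group are not exact.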

Other observations

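The receptor gene values and the test of B cell against T cell genes were chosen only after results had been seen.

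Receptor genes of the olfactory, vomeronasal and trace amine families, 584 measured genes that are not known as blood transcripts, moved nearly in one direction on the late days. On day 20, 497 were higher and 0 lower, and on day 30, 422 and 0, with median log2 fold changes of 1.19 and 0.98. On days 2, 3 and 5 they went both ways, with medians of -0.50, 0.31 and -0.44. Without scaling, their medians were 0.25 and 0.46 on days 20 and 30, while the 75th percentile of the exposed arrays differed from that of the controls by -0.94 and -0.53 on the log2 scale. The subtraction of the 75th percentile thus accounts by construction for 0.94 of the 1.19 on day 20 and 0.53 of the 0.98 on day 30.

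B cell genes may have fallen further than T cell genes, a pattern noticed in the data and tested on the same data. The B cell score minus the T cell score was lower in exposed than in control arrays by -0.89, -1.47, -1.43, -1.21 and -0.87 on days 2, 3, 5, 20 and 30. Exact two-sided permutation p was 0.00433, 0.0119, 0.0119, 0.00649 and 0.00216 (adjusted 0.0108, 0.0119, 0.0119, 0.0108 and 0.0108), where 0.0119 is the smallest that days 3 and 5 allow, and 5, 6, 6, 5 and 6 of the 6 exposed arrays were below all controls. A loss of B cells ahead of T cells and lower expression per cell cannot be told apart, since the test restates the pattern and no cell counts were given in the labels.

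Shared controls were checked as a source of overlap between days. Days 2 and 3 shared 787 changed genes and days 2 and 5 shared 1027, and in 20 simulations with shared controls and no change the median was 0, which says little since few genes then pass. The covariance of the changes was 0.0228 for days 2 and 3 and 0.248 for days 2 and 5, where the simulations gave 0.0469 and 0.0471 (correlations 0.063 and 0.532, simulated 0.408 and 0.408). For days 2 and 3 over all genes it was thus no larger than shared controls alone give. No 2 arrays held the same values in more than 0.00255% of spots.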
